A study of Temora longicornis with 12 samples.

How the data were processed

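Whole adult copepods were the source of total RNA, from which stranded poly(A) libraries were prepared and sequenced as paired-end reads on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name Trim Galore 0.4.1, TopHat2 2.1.1, HTSeq 0.6.1 and edgeR, without stating the role or order of each. The deposited values are raw read counts per assembled transcript, as whole numbers with a different total in each library. Identifiers have the form written by the Trinity assembler. The assembly and its annotation, the counting options and any filter on transcripts are not given in the sources used here. Reads shared between near-identical transcripts of one assembly may have been split or dropped by the counting, so single transcripts of a family are uncertain.

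Libraries were grouped by the treatment in the labels into control, acute, sustained and recovery groups of 3. Replicate numbers follow the order of deposit and do not pair libraries between groups. The labels give vessels as the replicates, so p-values measure the spread between vessels of animals. Counts of replicate libraries differed by 12.6 to 41.4 times the sampling noise (chi-square per degree of freedom), so no replicate library was a repeat of another of its group.

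Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust dispersion, TMM scaling, the default low-count filter (minimum count 10, minimum total 15) and all 4 groups in one fit with 8 residual degrees of freedom. TMM factors ranged from 0.634 to 1.34, and the biological coefficient of variation was 37%. P-values were adjusted by the Benjamini-Hochberg method over the 40943 transcripts tested, with a threshold of 0.05. The groups, tests, named-transcript rule and most other settings were fixed before the data were examined. CPM values are counts scaled to library totals, computed from the deposited counts after TMM scaling. Under other observations, and for ranges of more than 10-fold within a group, CPM was instead scaled to totals without TRINITY_DN157064_c6_g3_i1 and without TMM. Steps and ranges of 10-fold were taken after adding 0.2 CPM, and 8-fold deviations after adding 0.5 CPM. The prior count for fitted fold changes was 0.125, and 2 for log2 CPM in the principal components. Standard errors (SE) were derived as the fitted log2 difference divided by the square root of its F statistic. The 95% intervals of differences rest on these, so both are approximate. Libraries were compared with a permutation test on distances in log2 CPM, with 100000 permutations for all groups and exact enumeration for pairs. Shares of counts in single libraries carry 95% Wilson intervals, which cover counting error only, since reads are not independent molecules.

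Other settings chosen in advance were DESeq2 1.42.0, edgeR's exact test, RLE factors, library totals alone, no low-count filter, a filter of at least 1 CPM in 3 libraries, thinning to the smallest total, fits of only the groups compared and leaving out each library in turn. Settings chosen after the data were seen were voom with library quality weights in limma 3.58.1, counts summed by Trinity gene identifier, leaving out the transcript with the largest share of counts, leaving out control replicate 2 from every fit and leaving out control replicate 2 with acute replicate 3.

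The planned rule for named transcripts required an adjusted p under 0.05 in the main test and gave none. The transcripts named for each pair of groups were therefore chosen after their values were seen, as the transcript with the smallest unadjusted p in each direction; TRINITY_DN188408_c1_g11_i1, TRINITY_DN165620_c1_g3_i1, TRINITY_DN138463_c0_g1_i2, TRINITY_DN187780_c4_g3_i1 and TRINITY_DN157064_c6_g3_i1 were added because another setting called them or because of their share of counts. Such a choice favours large estimates. Planned gene lists were not tested, because the deposited table does not pair identifiers with gene names and no reference was used here.

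The edgeR test was tested on simulated data with the libraries' own totals and each transcript's mean over all libraries. In a simulated acute against control comparison of 40943 transcripts, 50 were changed at each fold size, all with a mean above 1 CPM. Of these, 12% were recovered at 2-fold, 78% at 4-fold, 88% at 8-fold and 94% at 16-fold, with 8 false calls. No simulated library was made to stand apart as control replicate 2 does, and no transcript of lower level was changed. The shares therefore may not hold for the real data. Splits and patterns were summarised with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots were drawn with matplotlib 3.10.9.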

Results

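Expression was measured by RNA sequencing in whole adults of Temora longicornis, a small marine planktonic crustacean, after 5 days at a lower or a raised temperature with or without a change of temperature on the last day. The control group was held at 14 °C throughout. The acute group spent 4 days at 14 °C and the last 24 h at 17 °C. The sustained group was brought to 17 °C over 24 h and stayed there until the end. The recovery group was treated like the sustained group and was returned to 14 °C for the last 24 h. Total exposure was 120 h in every group. Each group had 4 vessels, of which 3 were sequenced, which gave 12 libraries with 3 per group. The total count per library ranged from 11582848 in control replicate 2 to 32504862 in recovery replicate 2. The table held 44985 assembled transcripts, of which 144 had a count of 0 in every library and 40943 had enough counts to be tested. Transcripts carried assembly identifiers that the deposited table does not pair with gene names, so each is given by its identifier alone, with no position or function.

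The first question was how far the libraries of a group resembled each other. Control replicate 2 stood apart from the other 11 libraries. Its median Spearman correlation with them across transcripts was 0.833, with a range from 0.812 to 0.897, the highest being with acute replicate 3 and the next 0.843, whereas the other 11 libraries correlated with each other between 0.898 and 0.953. The first principal component of log2 CPM (CPM, counts scaled to the library total), with 31.8% of the variance, separated control replicate 2 from all others, and the second held 12.2%. Group membership accounted for 27.3% of the variation in expression, the share that random assignment gives on average (pseudo-F = 1, permutation p = 0.39, 100000 permutations, one-sided), and for 30.9% without control replicate 2, where random assignment gives 30% (permutation p = 0.32). In pairs of groups, sustained against control and sustained against acute each had an exact permutation p of 0.1, the smallest that 3 libraries against 3 allow, and the other 4 pairs had exact permutation p-values from 0.5 to 1. Over the 500 most variable transcripts the exact permutation p was 0.2 for sustained against control, 0.1 for sustained against acute and 0.3 to 0.8 for the other pairs.

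**Figure D1:**
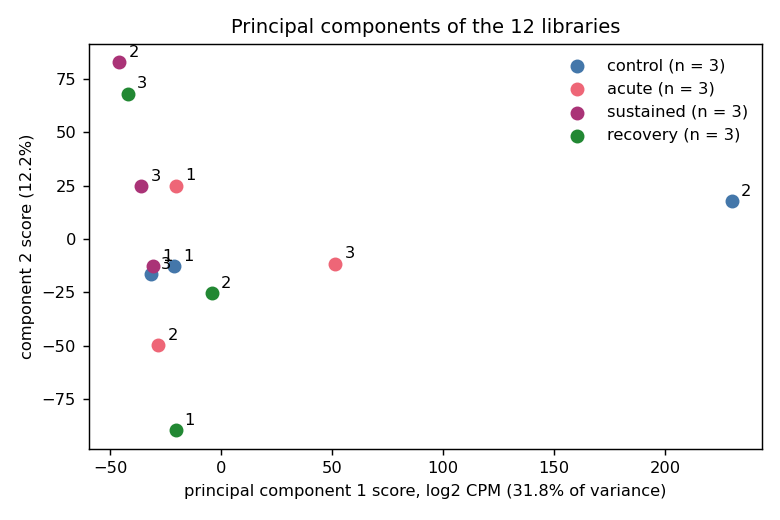
Scores of the 12 libraries on the first and second principal components of log2 CPM, in units of the component scores, coloured by group and numbered by replicate (n = 3 per group). Control replicate 2 lies at 230 on the first axis, and the next highest library, acute replicate 3, lies at 51.4.

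A single transcript, TRINITY_DN157064_c6_g3_i1, singled out after its values were seen, took a large and uneven part of the counts. Its share was 17.1% ± 14.8 (SD, n = 3) in the control group, 14.4% ± 13 in the acute group, 23.4% ± 18.7 in the sustained group and 39.9% ± 18.1 in the recovery group. Single libraries ranged from 0.00387% in control replicate 3 (95% Wilson interval 0.003604% to 0.004156%, counting error only) to 53.1% in recovery replicate 1 (53.08% to 53.11%). The lowest of the 6 two-sided exact permutation p-values between pairs of groups was 0.2, for recovery against acute, and 0.1 is the lowest that 3 libraries against 3 allow, so this design cannot pass 0.05.

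**Figure D2:**
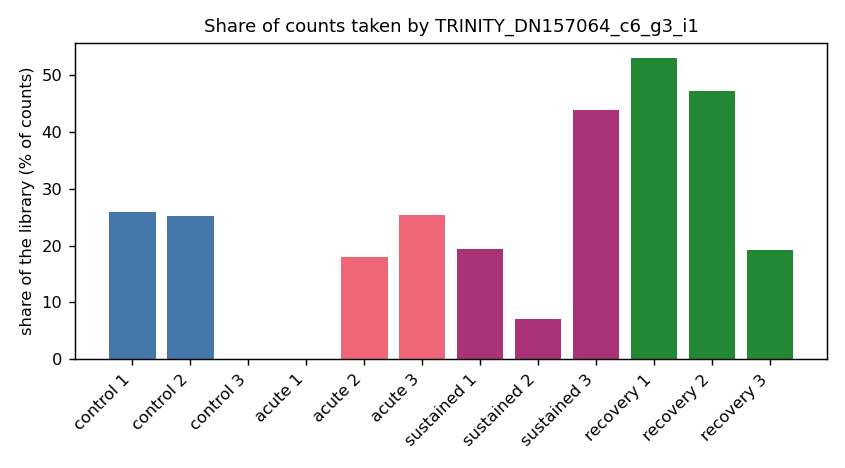
Share of each library's counts, in percent, taken by the transcript TRINITY_DN157064_c6_g3_i1, with 1 bar per library coloured by group. The bars of control replicate 3 and acute replicate 1 are at 0.00387% and 0.009864%, and that of recovery replicate 1 is at 53.1%.

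The comparison of the acute group with the control group asked what changed within 24 h of warming. The transcript TRINITY_DN191068_c4_g2_i10 was at 1.09 ± 0.0385 CPM (SD, n = 3) in the control group and at 3.75 ± 0.726 CPM in the acute group. The log2 difference was 1.78 ± 0.30 (SE), and the sustained and recovery groups were at 1.19 ± 0.0185 and 1.43 ± 0.226 CPM. Its counts were 27, 13 and 29 in the control libraries and 38, 28 and 27 in the sustained libraries. Counting error at such counts exceeds the SDs of these groups, so those SDs understate the spread. The transcript TRINITY_DN117508_c0_g2_i1 was lower after the acute exposure, at 30.6 ± 4.49 CPM against 64.8 ± 13.2 CPM, a log2 difference of -1.08 ± 0.18. All 3 acute libraries lay outside the range of the control libraries for both transcripts, which their choice by smallest p made likely in advance. Neither passed edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.74 for each), and DESeq2 called both (adjusted p = 0.0041 and 0.0097). Across 40943 transcripts, edgeR's quasi-likelihood test called 0. Its unadjusted p was under 0.05 for 1596 (797 without acute replicate 1 and 3141 without acute replicate 3). Evenly spread p-values would give 2047. Other splits of the same libraries gave 767 to 3337, so 2047 is no firm measure of chance here or in the other pairs. DESeq2 called 3, edgeR's exact test 2 and limma voom with quality weights 0. Of the 3 transcripts called by DESeq2, 0 spanned more than 10-fold within a group. The 2 called by the exact test were TRINITY_DN191068_c4_g2_i10 (adjusted p = 0.0037) and TRINITY_DN188408_c1_g11_i1 (adjusted p = 0.017), the latter also the remaining call of DESeq2 (adjusted p = 0.00093). This transcript was at 10.4 ± 7.47 CPM in the control group and 1.06 ± 0.491 CPM in the acute group. It was at 1.86 CPM in control replicate 2 against 15.7 and 13.6 CPM in the other control libraries, and without control replicate 2 it was the 1 transcript that the quasi-likelihood test of edgeR called (log2 difference -3.80, adjusted p = 0.0023). The 95% interval of the difference lay within 4-fold for 79.6% of transcripts and within 2-fold for 35.3%.

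**Figure D3:**
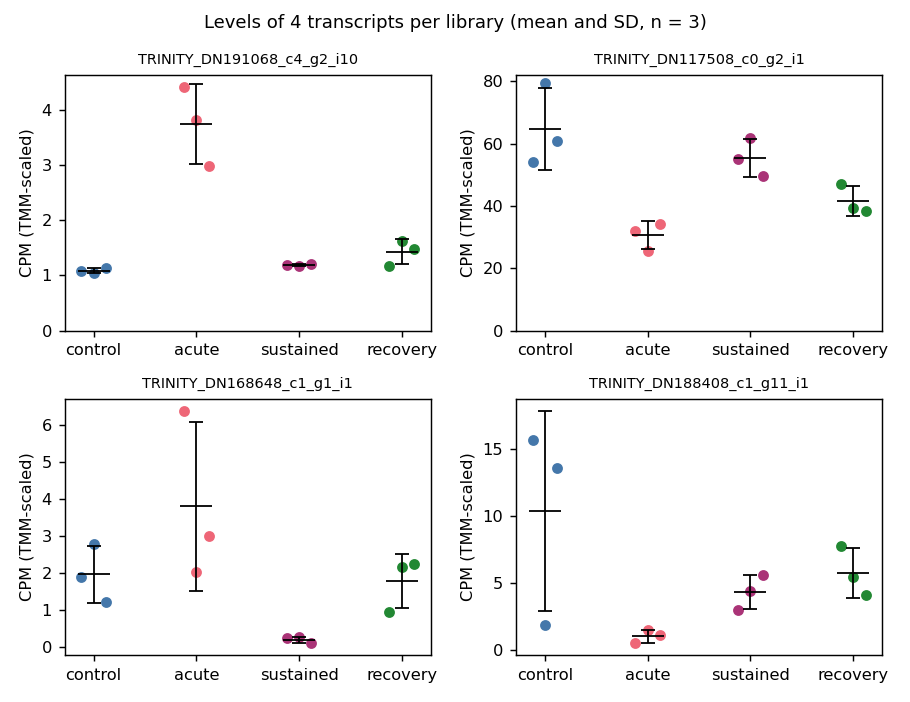
Levels of 4 transcripts in each library, in CPM after TMM scaling on linear axes, by group (points, 3 libraries per group; bars, mean and SD). TRINITY_DN191068_c4_g2_i10 lies at 3.75 CPM in the acute group and 1.09 CPM in the control group, and TRINITY_DN168648_c1_g1_i1 at 0.187 CPM in the sustained group and 1.95 CPM in the control group; no difference passed edgeR's quasi-likelihood test with all 12 libraries.

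The comparison of the sustained group with the control group asked what differed after 5 days with warming. The transcript TRINITY_DN138837_c0_g1_i1 was at 3.08 ± 1.59 CPM in the sustained group and 0.46 ± 0.289 CPM in the control group (SD, n = 3), a log2 difference of 2.63 ± 0.55 (SE). The transcript TRINITY_DN168648_c1_g1_i1 was at 0.187 ± 0.0857 CPM in the sustained group and 1.95 ± 0.777 CPM in the control group, a log2 difference of -3.30 ± 0.59, from counts of 2 to 7 per sustained library. Neither passed edgeR's quasi-likelihood test (adjusted p = 0.98 for each). DESeq2 called both (adjusted p = 0.016 and 0.0012 in that order), and the lower one was the single call of edgeR's exact test (adjusted p = 0.0087). The quasi-likelihood test in edgeR called 0 transcripts. Its unadjusted p was under 0.05 for 1819 (944 without sustained replicate 2), where evenly spread p-values would give 2047. DESeq2 called 15, edgeR's exact test 1 and limma voom with quality weights 0. Of the 15 transcripts called by DESeq2, 7 spanned more than 10-fold between libraries of the same group.

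The comparison of the recovery group with the control group asked what still differed 24 h after the return to 14 °C. The transcript TRINITY_DN183058_c2_g2_i1 was at 55.7 ± 5.45 CPM in the recovery group and 31.2 ± 5.76 CPM in the control group (SD, n = 3), a log2 difference of 0.83 ± 0.17 (SE). The transcript TRINITY_DN183421_c3_g2_i1 was at 0.0592 ± 0.0344 CPM against 1.23 ± 0.162 CPM, a log2 difference of -4.32 ± 0.80, with 1 or 2 counts in each recovery library. Neither passed edgeR's quasi-likelihood test (adjusted p = 1 for each), although edgeR's exact test called TRINITY_DN183421_c3_g2_i1 (adjusted p = 0.025). The quasi-likelihood test in edgeR called 0 transcripts. Its unadjusted p was under 0.05 for 1302 (2146 without control replicate 3, and 3549 when scaled by library totals alone). Evenly spread p-values would give 2047. DESeq2 called 1, the exact test 1 and limma voom with quality weights 0. The call of DESeq2 was TRINITY_DN138463_c0_g1_i2, with counts of 146, 0 and 292 in the control libraries and 0 in each recovery library.

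The comparison of the recovery group with the sustained group asked what a last day at 14 °C changed in warmed animals. The transcript TRINITY_DN168648_c1_g1_i1, low in the sustained group, was at 1.77 ± 0.724 CPM in the recovery group, close to the 1.95 ± 0.777 CPM of the control group (SD, n = 3), with a log2 difference of 3.19 ± 0.59 (SE) from the sustained group. The transcript TRINITY_DN168883_c0_g1_i1 was at 25.3 ± 6.11 CPM in the recovery group and 61.2 ± 16.8 CPM in the sustained group, a log2 difference of -1.28 ± 0.22. Neither passed edgeR's quasi-likelihood test (adjusted p = 1 for each); edgeR's exact test called TRINITY_DN168648_c1_g1_i1 (adjusted p = 0.025), and DESeq2 called both (adjusted p = 0.0036 and 0.0069). The quasi-likelihood test in edgeR called 0 transcripts. Its unadjusted p was under 0.05 for 877 (550 without sustained replicate 2 and 2316 without recovery replicate 3). Evenly spread p-values would give 2047. DESeq2 called 9, the exact test 1 and limma voom with quality weights 0. Of the 9 transcripts called by DESeq2, 5 spanned more than 10-fold between libraries of the same group. Because no transcript passed the test between the sustained and control groups, the share of that response undone in the recovery group had no value.

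The comparison of the sustained group with the acute group asked how 5 days with warming differed from 24 h of it. The transcript TRINITY_DN168648_c1_g1_i1 was at 0.187 ± 0.0857 CPM in the sustained group and 3.79 ± 2.29 CPM in the acute group (SD, n = 3), a log2 difference of -4.28 ± 0.59 (SE). Its adjusted p of 0.14 in edgeR's quasi-likelihood test was the lowest of any pair of groups. It was 0.048 without control replicate 2, which enters this comparison only through the shared estimate of the spread, the filter and the scaling. In the same test, the lowest adjusted p of any transcript was 0.57, 0.088 and 0.15 without acute replicate 1, 2 and 3 in turn. That lowest value was 0.076 without both control replicate 2 and acute replicate 3, and 0.92 or more without any 1 sustained library. The transcript TRINITY_DN166838_c0_g1_i1 was at 1.76 ± 0.953 CPM against 0.0826 ± 0.0347 CPM, a log2 difference of 4.30 ± 0.83 (edgeR quasi-likelihood adjusted p = 0.94), from counts of 1 to 3 per acute library. Both were called by edgeR's exact test (adjusted p = 1.1e-06 and 0.01) and by DESeq2 (adjusted p = 2.2e-07 and 0.007). The quasi-likelihood test in edgeR called 0 transcripts. Its unadjusted p was under 0.05 for 2044 (1053 without sustained replicate 2), where evenly spread p-values would give 2047. DESeq2 called 23, the exact test 9 and limma voom with quality weights 0. Of the 23 transcripts called by DESeq2, 10 spanned more than 10-fold between libraries of the same group, as did 1 of the 9 called by the exact test.

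The comparison of the recovery group with the acute group set both orders of the 2 temperatures side by side. The transcript TRINITY_DN191373_c3_g8_i1 was at 772 ± 129 CPM in the recovery group and 439 ± 63.4 CPM in the acute group (SD, n = 3), a log2 difference of 0.81 ± 0.17 (SE). The transcript TRINITY_DN191068_c4_g2_i10 was at 1.43 ± 0.226 CPM against 3.75 ± 0.726 CPM, a log2 difference of -1.39 ± 0.29. Neither passed edgeR's quasi-likelihood test (adjusted p = 1 for each), and neither DESeq2 nor edgeR's exact test called them. The quasi-likelihood test in edgeR called 0 transcripts. Its unadjusted p was under 0.05 for 1601 (967 without acute replicate 1, 2425 without acute replicate 3, and 5497 when scaled by library totals alone). Evenly spread p-values would give 2047. DESeq2 called 1, the exact test 1 and limma voom with quality weights 0. The call of DESeq2 was the same transcript as against the control group, with counts of 231, 0 and 0 in the acute libraries. The call of edgeR's exact test was TRINITY_DN187780_c4_g3_i1 (adjusted p = 0.011), with counts of 34, 23 and 24 in the acute libraries and 0, 0 and 4 in the recovery libraries.

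The 2 temperatures were then treated as separate factors, each averaged over the other. The transcript TRINITY_DN188408_c1_g11_i1 had a log2 difference of -1.86 ± 0.44 (SE) between last days at 17 °C and at 14 °C (edgeR adjusted p = 1), and of -2.10 without control replicate 2, when edgeR's quasi-likelihood test called it (adjusted p = 0.02). For the temperature of the last day, edgeR's quasi-likelihood test called 0 transcripts with all libraries, with 1186 at an unadjusted p under 0.05 (773 without acute replicate 1, 2165 without acute replicate 3, 1812 without recovery replicate 3 and 1799 without control replicate 2), and DESeq2 and limma voom also called 0. For the temperature of the first 4 days it called 0, with 2184 at an unadjusted p under 0.05 (5172 when scaled by library totals alone); DESeq2 called 36, of which 21 spanned more than 10-fold within a group, and limma voom 0. Without control replicate 3, edgeR called the transcript TRINITY_DN165620_c1_g3_i1 for the first 4 days (log2 difference -5.04, adjusted p = 0.019); its control counts were 82, 49 and 2, and the 2 was in the library left out. For the interaction of the factors edgeR's quasi-likelihood test called 0, with 1184 at an unadjusted p under 0.05 (2097 without acute replicate 3, 2670 without recovery replicate 3 and 1813 without control replicate 2); DESeq2 called 6, of which 2 spanned more than 10-fold within a group, and limma voom 0. For any difference among the 4 groups edgeR's test called 0, with 1231 at an unadjusted p under 0.05; DESeq2 called 10, of which 1 spanned more than 10-fold within a group, and limma voom 0. The 95% interval lay within 4-fold for 94% of transcripts for the last day for 92.7% for the first 4 days and for 59.9% for the interaction, where 17.5% lay within 2-fold.

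Whether the temperature of one phase had like effects at both temperatures of the other phase was asked by correlating log2 differences. These were taken across the 40943 transcripts, which are not independent replicates. For the last day and for the first 4 days, a response to any change of temperature would enter the 2 differences with opposite signs. Such a response would lower r, so r does not measure whether a change itself acted alike. The differences of the last day (acute minus control, and sustained minus recovery) had a Pearson r of -0.0127 and a Spearman rho of 0.00562, and 49.2% of transcripts had the same sign. This r ranged from -0.194 without control replicate 2 to 0.0719 without recovery replicate 2, with an SD of 0.198 over 100 regroupings of the libraries. The differences of the first 4 days (recovery minus control, and sustained minus acute) had r = 0.234 and rho = 0.129, with 53% of the same sign. This r was -0.116 without control replicate 2, 0.0865 without recovery replicate 3, 0.0917 without acute replicate 3 and 0.456 without recovery replicate 2. It therefore depended on more than 1 library. The 200 transcripts most different in either direction in one comparison were tested in the other with limma's fry, and none of the 8 sets passed (lowest adjusted p = 0.54). The acute and sustained groups share their controls, and their differences from control had r = 0.404, rho = 0.465 and a covariance of 0.165. In 20 simulations, acute and sustained libraries were drawn from the mean of the acute, sustained and recovery libraries, against the same controls. There r was 0.586 ± 0.004 (SD) and the covariance 0.255 ± 0.0032, an SD between simulations that leaves out the choice of libraries. A response common to those groups would be part of these values. They therefore cannot show whether the real r holds a shared response. Over 100 regroupings of the libraries, r ranged from 0.184 to 0.784 (SD 0.147), and 71 gave at least 0.404.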

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

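The tests with limma voom, with summed counts, without the dominant transcript, and with control replicate 2 removed from every fit were chosen after the result was seen. Counts of called transcripts were 0 in every comparison with edgeR's quasi-likelihood test under RLE factors, library totals, no low-count filter, the stricter filter, thinning, a fit of only the groups compared (run for the 6 pairs alone), summed counts and removal of the dominant transcript or of both control replicate 2 and acute replicate 3, and with limma voom. DESeq2 called 3 transcripts for acute against control, 15 for sustained against control, 1 for recovery against control, 9 for recovery against sustained, 23 for sustained against acute, 1 for recovery against acute, 36 for the first 4 days, 6 for the interaction and 10 for any difference; it called 0 for the last day. The exact test of edgeR called 2, 1, 1, 1, 9 and 1 in the 6 pairs in the same order. Some calls of DESeq2 had a step of more than 10-fold between libraries, a pattern described under other observations. These were 4 of 9 for recovery against sustained, 4 of 23 for sustained against acute and 3 of 15 for sustained against control. They were 4 of 36 for the first 4 days, 0 of 3 for acute against control and 0 of 10 for any difference. The cause of the differences between tests was not tested. The number at an unadjusted p under 0.05 moved more. Library totals include the dominant transcript, at a mean of 39.9% of counts in the recovery group, 17.1% in the control group and 14.4% in the acute group. Without TMM, a larger share of it makes every other transcript look lower. Counts scaled this way are therefore no added evidence of change. Scaled by library totals alone, the number at an unadjusted p under 0.05 was higher for recovery against acute (5497), recovery against control (3549), the first 4 days (5172) and any difference (1874). It was lower for acute against control (760), sustained against control (1179) and the interaction (723). Over all settings it ranged from 760 to 3141 for acute against control, 944 to 2548 for sustained against control, 678 to 3549 for recovery against control, 550 to 2316 for recovery against sustained, 1053 to 3753 for sustained against acute, 967 to 5497 for recovery against acute, 773 to 2422 for the last day, 1606 to 5172 for the first 4 days, 723 to 2683 for the interaction and 832 to 2253 for any difference.

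Each library was left out in turn, for a pair of groups only the libraries of that pair and control replicate 2. These fits gave 0 to 1 called transcripts by edgeR for any difference, acute against control, sustained against acute, the last day and the first 4 days, and 0 in the other comparisons; the single calls came without control replicate 2, except for the first 4 days, where it came without control replicate 3. For agreement over the first 4 days, r ranged from -0.116 without control replicate 2 to 0.456 without recovery replicate 2. For acute and sustained against the same control it was 0.404 with all libraries and ranged from 0.295 without acute replicate 2 to 0.607 without control replicate 3, with 0.556 without control replicate 1. The cause was not tested. No paired analysis was possible because replicate numbers do not link libraries across groups.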

Other observations

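All tests in this part except the correlation of the lowered transcripts over the other 11 libraries were chosen after the result was seen.

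Among transcripts with a median above 2 CPM in the other libraries, control replicate 2 differed mostly by loss. Gains from a lower level are not counted here, such as most of the 81 transcripts given further on as over 10-fold higher in it. Of 23118 transcripts with a median above 2 CPM in the other libraries, 702 (3%) were at least 8-fold lower in control replicate 2 and 29 at least 8-fold higher, where each other library had between 3 and 24 that were lower. Fewer reads do not account for this: with every library thinned to the smallest total, control replicate 2 had 695 such transcripts and the highest of the others had 26. RNA of one source that this library lacks, and that varies in amount over the other libraries, is argued against. Over those libraries the lowered transcripts had a median pairwise correlation of 0.021, within the 0.004 to 0.032 of 100 sets matched for expression. A source in near-constant amount would give no such correlation, so it stays open. A loss tied to transcript sequence, as a genetic variant might give, stays open: other transcripts of the same Trinity gene identifier deviated by a median log2 of -1.15 (quartiles -3.21 and 0.11; 245 transcripts), and by -0.20 when the 70 that were themselves 8-fold lower are left out, so the choice decides the value, and no biological explanation from the design was tested for a single library.

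For the uneven share of TRINITY_DN157064_c6_g3_i1, RNA of another organism with several transcripts in the table was considered as a source. In both low libraries, 6 other transcripts were under 10% of a median above 2 CPM over the other 10 libraries. That count was reached by 24 of the 65 other pairs of libraries (highest 19), so it is no sign of such a source. Of 17046 transcripts above 2 CPM in all of the other 10 libraries, 0 were under 10% of their median in both low libraries. This argues against a source with several transcripts at that level. Another organism whose other transcripts were at lower levels stays open. Temperature treatment alone is argued against, since the highest share was at least 2570 times the lowest within the control group and within the acute group. A part played by temperature stays open: the share was 31.6% ± 18.8 (SD, n = 6) after a first phase at 17 °C and 15.7% ± 12.5 after 14 °C (two-sided exact permutation p = 0.102, adjusted over both temperatures 0.203). By the last day it was 18.9% ± 15.2 at 17 °C and 28.5% ± 19.3 at 14 °C (exact permutation p = 0.329, adjusted 0.329).

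A set of 445 transcripts had a step of more than 10-fold between libraries, of which 396 were low in control replicate 2 alone. A further 18 were high in control replicate 2, acute replicate 1, acute replicate 3 and recovery replicate 2, where their summed levels were 1270, 740, 1110 and 397 CPM, against 6.6 CPM or less in each other library. Temperature treatment alone is argued against by 81 transcripts picked from the control libraries alone, as over 10-fold higher in control replicate 2. Their summed level differed at least 24.9-fold between the acute libraries and between the recovery libraries. Of the 18, 17 were among them, which the 2 rules of choice made likely in advance, so this overlap adds no support. A single source of RNA in changing amounts cannot be told apart from separate causes. Such a source could be food or another organism carried with the animals. The SD of log2 ratios between pairs of these libraries was 1, against 0.33 to 1.58 in 100 matched sets (median 0.64). The ratios were thus kept no better than in the median matched set, which gives no sign of a single source.

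Other splits of the libraries were compared by the number of transcripts at an unadjusted p under 0.05 in edgeR's quasi-likelihood test, since no transcript was called. Each pair of groups allows 10 splits, too few for a share under 0.05. For acute against control 6 of the 10 splits gave at least the real 1596 (highest other 3337), for sustained against control 3 gave at least 1819 (highest other 1918), and for recovery against control 9 gave at least 1302 (highest other 3317). For recovery against sustained 7 gave at least 877 (highest other 4322), for sustained against acute only the real split gave 2044 (1 split; highest other 2034), and for recovery against acute 6 gave at least 1601 (highest other 2668). Among 100 regroupings of the 12 libraries, chance could not be excluded: 60 gave at least the real 1231 for any difference (highest other 4321), 72 at least 1186 for the last day (highest other 4758), 25 at least 2184 for the first 4 days (highest other 4634) and 66 at least 1184 for the interaction (highest other 5247). An r at least as far from 0 as the 0.234 between the differences of the first 4 days came from 29 of the 100. Most regroupings, like the real groups, called 0 transcripts: 14 called any for any difference among groups (at most 75) and 9 for the first 4 days (at most 52).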
